A study of Homo sapiens with 12 samples.

How the data were processed

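RNA-seq was measured in 12 libraries of HT1080 cells, an established human fibrosarcoma line with a mutant NRAS gene. There were 4 groups of 3 libraries: control siRNA (siNC) or siRNA against NRAS Q61K (siQ61K), each with DMSO or with poly(dA:dT), a synthetic double-stranded DNA that triggers cytosolic DNA sensing. Groups and replicate numbers came from the sample titles. The columns of the series table carry short names, which were matched to the titles by reading the only other siRNA and the only added agent into them; that reading is an inference from names. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

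The authors deposited 1 table of TPM, a relative abundance scaled for transcript length, per gene symbol. Per the labels' protocols, total RNA was made into libraries with a NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq. Salmon 0.8.0 and the hg19 build are named in the submitters' processing notes. The annotation and the way transcripts were summed to genes are not given in the sources used here. TPM keeps no depth, so the depth of each library is unknown and no counting interval is given. The table held 56227 entries, of which 984 shared 58 symbols (730 of them named Y_RNA) and were left out. No coordinates are given, because the reference used here for gene type, length and GC content (GENCODE release 29) is on another build than the submitters' notes name.

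Deposited TPM values were analysed as log2(TPM + 1) for the 14722 genes with at least 1 TPM in at least 3 of the 12 libraries. A fold change on this scale understates the change of low genes. All 4 groups entered 1 linear model in limma 3.58.1 (R 4.3.3), with a variance trend and Benjamini-Hochberg adjustment over all genes at 0.05. The comparisons were siQ61K against siNC without and with poly(dA:dT), poly(dA:dT) against DMSO under each siRNA, and the interaction, which is the poly(dA:dT) response under siQ61K minus that under siNC. Standard errors (SE) are those of the model. Single values were also compared by exact two-sided permutation tests, which cannot go below p = 0.1 for 3 libraries against 3.

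Before the data were examined, 19 gene lists with 540 members in all were fixed: interferon-alpha response, core interferon-stimulated genes, type I and III interferons, interferon receptor signalling, cytosolic nucleic acid sensing, NF-kB and inflammatory genes, T-cell chemokines and checkpoint ligands, antigen presentation, ERK pathway target genes, RAS pathway components, cell division, p53 target genes, endoplasmic reticulum and integrated stress, BCL2 family, extracellular matrix and mesenchymal genes, sterol and fatty acid synthesis, mitochondrially encoded mRNAs, ribosomal protein genes, and markers of other cell types. Each list was compared with all other genes by camera with a preset correlation of 0.01 and again with a correlation estimated from its own members, adjusted over the 19 lists of a comparison. Calls of list members were also made with p-values adjusted over the list alone. The rule for genes named in the text was fixed at the same time. It takes NRAS, the 10 highest and 10 lowest called genes of a comparison with a mean of at least 5 TPM in the higher group and, except for the interaction, no overlap of values, up to 4 called members of each list, and a fixed set of interferon, cGAS-STING, ERK and RAS genes. Results for some genes of that rule are not reported here.

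Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, mitochondrial genes left out, no variance trend, a robust trend, sample weights, a fit to only the groups compared, a replicate block and leaving out each library. Added after the data were seen were a smooth correction of each library for GC content and length of the longest transcript (lowess, span 0.3), the first principal component of the residuals as a covariate, and a fit without siQ61K DMSO replicate 3 and siQ61K poly(dA:dT) replicate 2. GC content was known for 14299 of the 14722 genes (97.13%). In camera a variance trend was used for the deposited values but not for the corrected ones, so their list p-values differ in that setting too.

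The fit was tested on simulated values for 14722 genes, with 200 changed. For the comparison without poly(dA:dT), 97% of genes changed by 2 on the log2 scale, 61.2% of those changed by 1 and 13.4% of those changed by 0.5 were recovered, with 6 false calls. For the interaction the shares were 80.3%, 31.3% and 0%, with 7 false calls. Errors in these simulations were independent between genes, with no GC trend and no shared residual component. Their false calls therefore do not carry over to the counts reported below. With a simulated GC trend in each library, the interaction gave 6812 false calls without the GC and length correction and 13 with it, and recovered 183 of 200 and 168 of 197 changed genes. That trend was linear in GC content with independent errors, a form that the correction removes by design. It held no real GC-linked response and no shared residual component, so it does not test the correction on these data.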

Results

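Gene expression was measured in HT1080 cells, a human fibrosarcoma line, after siRNA against mutant NRAS or a control siRNA, with poly(dA:dT) or DMSO. Each of the 4 groups had 3 libraries, and replicate libraries correlated at 0.966 to 0.984 across genes. The depth of the libraries is unknown because the deposited values are TPM. The study concerned the interferon-alpha response to knockdown of mutant NRAS.

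NRAS was lower in every siQ61K library than in every siNC library. Without poly(dA:dT), NRAS stood at 59.6, 60.6 and 41.4 TPM under siNC and at 15.5, 15.2 and 19.9 TPM under siQ61K. With poly(dA:dT) the values were 43.0, 45.9 and 51.7 TPM under siNC and 20.1, 20.3 and 23.5 TPM under siQ61K. The log2 fold change was -1.61 (SE 0.16, adjusted p = 2.54e-05) without poly(dA:dT) and -1.10 (SE 0.16, adjusted p = 0.000426) with it. The exact permutation test gave p = 0.1 in both, the smallest it can give. HRAS (log2 fold change 0.24, adjusted p = 0.191) was not called without poly(dA:dT), but turned to -0.23 and was called after the GC and length correction (adjusted p = 0.0466).

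**Figure D1:**
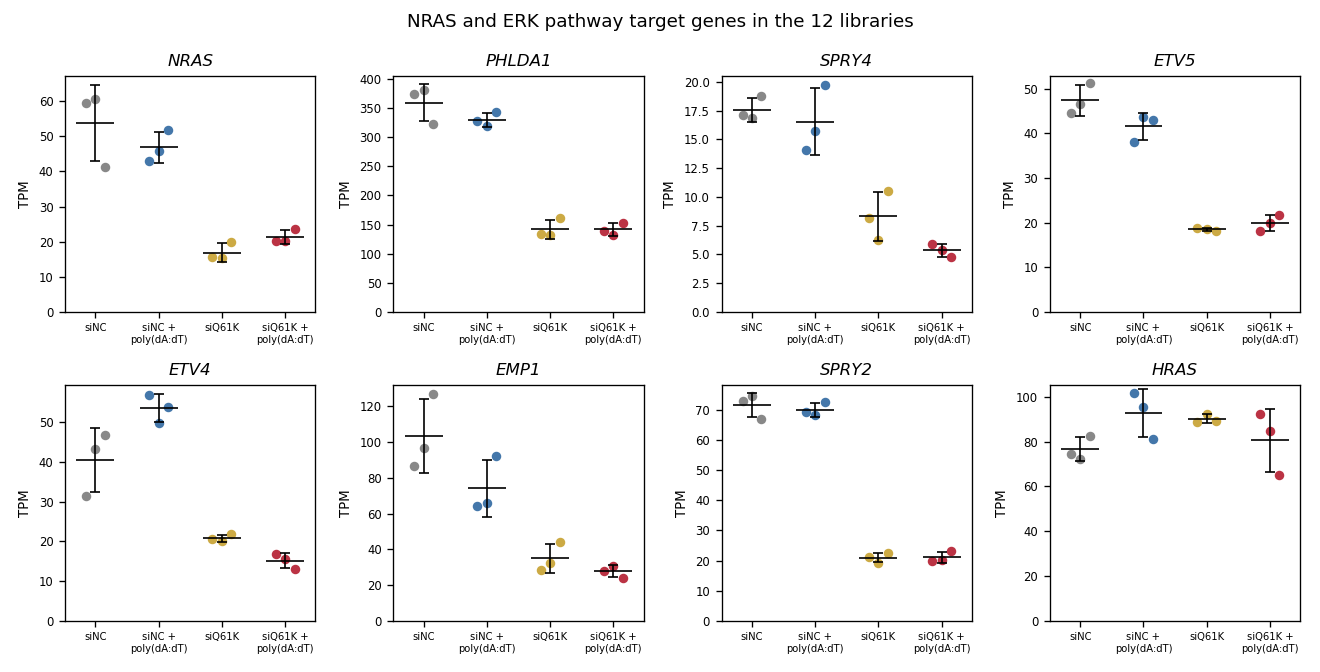
TPM of NRAS, the ERK target genes PHLDA1, SPRY4, ETV5, ETV4, EMP1 and SPRY2, and HRAS in the 4 groups; points are libraries and bars show the mean ± SD (n = 3). NRAS had a mean of 53.9 TPM in siNC DMSO and 16.9 TPM in siQ61K DMSO.

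The knockdown without poly(dA:dT) addressed what siQ61K did to unstimulated cells. NRAS TPM does not separate alleles, so loss of the mutant form was not measured directly. With siQ61K as the only siRNA against NRAS, other effects of that siRNA cannot be told apart from loss of NRAS. Many target genes of the ERK pathway, which RAS activates, fell. SPRY2, a feedback inhibitor of the pathway, went from 71.5 ± 3.95 to 21.0 ± 1.61 TPM (SD, n = 3), a log2 fold change of -1.72 (SE 0.11, adjusted p = 5.67e-07). PHLDA1 (-1.34), ETV5 (-1.31) and the growth factor gene TGFA (-1.67) fell as well, but DUSP6 (-0.555, SE 0.288, adjusted p = 0.162) was not called. Of 33 ERK targets tested, 19 fell, 2 rose and 12 were not called, and 20 fell when adjusted over the list alone. By camera that list had an adjusted p = 1.12e-11 with the preset correlation and 0.223 with the estimated one, which was 0.237. After the GC and length correction, where camera had no variance trend, the p with an estimated correlation was 0.00506. Cell division genes also fell, 26 of 37, with 1 higher, and the same counts were found when adjusted over the list alone. Among them were the mitotic cyclin CCNB1 (-1.47) and its kinase CDK1 (-1.44). The list had an adjusted p = 1.12e-11 with the preset correlation. With an estimated correlation it was 0.177, and 0.00446 after the correction.

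Inflammatory genes went both ways without poly(dA:dT). IL32 rose from 5.03 ± 0.441 to 73.2 ± 5.97 TPM (SD, n = 3; log2 fold change 3.62, SE 0.14, adjusted p = 1.77e-08), while IL1B fell from 280.5 ± 14.4 to 43.0 ± 3.33 TPM and the neutrophil chemokine CXCL8 fell by 2.60 on the log2 scale. Of 22 NF-kB and inflammatory genes, 9 rose and 5 fell, the same as when adjusted over the list alone. THBS1, an extracellular matrix glycoprotein, rose from 16.4 ± 2.91 to 135.8 ± 23.5 TPM, whereas the integrin ITGB1 fell by 1.57 on the log2 scale. In the extracellular matrix list 16 of 32 rose and 6 fell (16 and 7 adjusted over the list alone), with an adjusted p = 0.708 with an estimated correlation. After the GC and length correction 11 of 31 rose and 8 fell, and the median went from 0.41 to 0.16. Sterol and fatty acid synthesis genes were lower in 12 of 25 and higher in 2, also when adjusted over the list alone (adjusted p = 0.651 with an estimated correlation), with INSIG1 at -1.27 and IDI1 at -1.25.

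Some interferon-stimulated genes were already higher without poly(dA:dT). IFI6 rose from 13.9 ± 2.60 to 57.7 ± 6.43 TPM (SD, n = 3; log2 fold change 1.98, SE 0.16, adjusted p = 6.46e-06) and IFIT1 from 6.51 ± 0.591 to 20.2 ± 0.784 TPM. Of 93 interferon-alpha response genes 28 rose and 7 fell, 29 and 7 when adjusted over the list alone. The study named this response as an outcome in these samples, so the list is not independent evidence of its direction. The core list shared 21 genes with it and the antigen presentation list 8, so these lists are not separate evidence. The interferon-alpha list had an adjusted p = 0.651 with an estimated correlation, as did the core list, and both had 0.00813 with the preset correlation. Of the 32 core interferon-stimulated genes 11 rose and 2 fell, also when adjusted over the list alone. In antigen presentation 9 of 24 rose and none fell (9 and 1 adjusted over the list alone), including TAPBP (1.01, and 0.67 after the correction) and PSMB8 (0.76), with an adjusted p = 0.651 with an estimated correlation.

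In all, limma called 4632 of 14722 genes without poly(dA:dT), 2450 higher and 2182 lower. Fold changes followed GC content (Spearman 0.505 across genes): 1354 genes were higher and 107 lower among the 3575 genes with the highest GC, 106 and 1106 among the 3575 with the lowest, and 3951 were called after the correction, 2837 of them shared. Without siNC DMSO replicate 1 the count was 3045.

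With poly(dA:dT) present, knockdown raised interferon-stimulated genes far more. IFIT1 stood at 41.0 ± 8.73 TPM under siNC and 505.8 ± 57.0 TPM under siQ61K (SD, n = 3; log2 fold change 3.61, SE 0.15, adjusted p = 2.16e-08). IFI6 stood at 95.8 ± 20.1 and 1006 ± 96.3 TPM. The DNA and RNA handling genes SAMHD1 (2.37) and DDX58, the RNA sensor RIG-I (1.61), rose too. In the core list 30 of 32 rose and none fell, also when adjusted over the list alone (adjusted p = 0.0128 with an estimated correlation). The interferon-alpha response list had 59 of 93 higher and 2 lower, 62 and 3 adjusted over the list alone (adjusted p = 0.0164 with an estimated correlation), with the same limit on independence.

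Antigen presentation genes rose in 11 of 24 and fell in 1, 14 and 1 adjusted over the list alone (adjusted p = 0.0278 with an estimated correlation). HLA-B, an MHC class I heavy chain, rose from 22.9 ± 4.23 to 60.0 ± 5.66 TPM (SD, n = 3). T-cell chemokines and checkpoint ligands rose in 7 of 11 and fell in 1, also when adjusted over the list alone (adjusted p = 0.0712 with an estimated correlation, and 0.0316 after the GC and length correction). With poly(dA:dT), CXCL10 was at 1.20, 0.154 and 0.697 TPM under siNC and at 4.18, 5.22 and 4.29 TPM under siQ61K (log2 fold change 1.77, SE 0.26, adjusted p = 0.000415). STING1, the adaptor downstream of cGAS, fell (log2 fold change -1.21, SE 0.17, adjusted p = 0.000275). STING1 was also lower by knockdown without poly(dA:dT) (-0.52, SE 0.17, adjusted p = 0.0303). It had no GC content and was not in the corrected fit. With poly(dA:dT), CGAS (-0.27, adjusted p = 0.452) and SOS1, a RAS exchange factor (0.12, adjusted p = 0.759), were not called.

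ERK targets and cell division genes were lower with poly(dA:dT) as well. Of the ERK targets 24 of 33 fell and 1 rose, 27 and 1 adjusted over the list alone (adjusted p = 0.0356 with an estimated correlation), with the phosphatase DUSP5 at -1.91 and ETV4 at -1.76. In cell division 28 of 37 fell and 1 rose, 29 and 1 adjusted over the list alone (adjusted p = 0.0278 with an estimated correlation), with the kinase PLK1 at -1.62. Sterol and fatty acid synthesis had 15 of 25 lower and none higher, 17 and 0 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation, and 0.0323 after the GC and length correction). limma called 3144 genes, 1282 higher (40.78%) and 1862 lower, and 3871 after the GC and length correction. The share higher was 52.82% with median-of-ratios scaling and 51.17% with quantile normalization. Fold changes of the knockdown without and with poly(dA:dT) correlated across genes at Pearson 0.310 and Spearman 0.251. In both comparisons 580 genes were higher (213 by independent lists) and 672 lower (276), while 182 were called in opposite directions. After the GC and length correction 1002 were higher in both, 1108 lower in both and 70 opposite. Genes are not independent replicates.

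**Figure D2:**
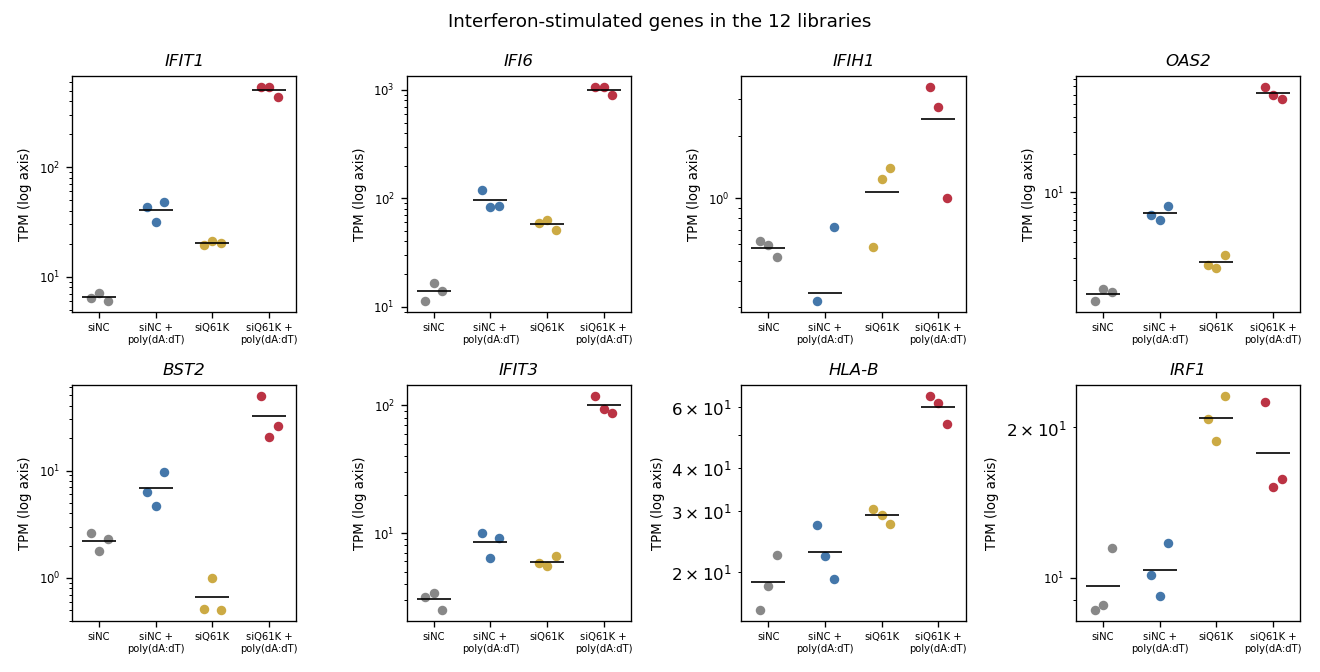
TPM on a log axis of IFIT1, IFI6, IFIH1, OAS2, BST2, IFIT3, HLA-B and IRF1 in the 4 groups; points are libraries and the line is the mean (n = 3). IFIH1 was 0 in siNC poly(dA:dT) replicate 2, which a log axis cannot show. IFIT1 averaged 6.51, 41.0, 20.2 and 505.8 TPM in siNC DMSO, siNC poly(dA:dT), siQ61K DMSO and siQ61K poly(dA:dT).

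Poly(dA:dT) under siNC tested the response to this agent under the control siRNA. The sample titles name no delivery control, so effects of delivery cannot be told apart from those of poly(dA:dT) under either siRNA. Under siNC, poly(dA:dT) raised a small set of interferon-stimulated genes. IFI6 rose by 2.69 (SE 0.16, adjusted p = 3.19e-06), IFIT1 by 2.46 (SE 0.15, adjusted p = 3.19e-06), OAS1 by 1.68, OAS2 by 1.61, IFITM1 by 1.59 and IRF9, an interferon-activated transcription factor, by 1.55 on the log2 scale. Of the core list 9 of 32 rose and none fell, 22 adjusted over the list alone (adjusted p = 0.0156 with an estimated correlation), and of the interferon-alpha response list 7 of 93 rose and none fell, 24 adjusted over the list alone (adjusted p = 0.0656 with an estimated correlation). After the GC and length correction the latter had 11 of 92 higher and an adjusted p = 0.00975 with an estimated correlation. No ERK target or cell division gene was called by limma. In all limma called 18 genes, 11 higher and 7 lower, against 1640 at an unadjusted p under 0.05. The count was 10, 9 and 7 without siNC DMSO replicates 1, 2 and 3, 7 without siNC poly(dA:dT) replicate 1, 37 without siQ61K poly(dA:dT) replicate 1, 29 after the GC and length correction and 332 with sample weights. Fold changes followed GC content here as well (Spearman 0.503 across genes), in the direction opposite to that under siQ61K (-0.572).

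Poly(dA:dT) under siQ61K tested the same response after knockdown, and interferon-stimulated genes rose strongly. IFIT1 rose by 4.57 (SE 0.15, adjusted p = 2.45e-09), OAS2 by 4.05 (SE 0.16) and IFI44 by 4.07 (SE 0.14) on the log2 scale. In the core list 29 of 32 rose and none fell, 30 adjusted over the list alone (adjusted p = 0.0038 with an estimated correlation), and in the interferon-alpha response list 56 of 93 rose and 3 fell, 59 and 5 adjusted over the list alone (adjusted p = 0.00872 with an estimated correlation). In cytosolic nucleic acid sensing 7 of 26 rose and 7 fell, also when adjusted over the list alone, with DDX58 at 2.71 and IFI16, a DNA sensor, at 1.48 (adjusted p = 0.587 with an estimated correlation). After the GC and length correction 7 of 25 rose and none fell, with an adjusted p = 0.0406. In interferon receptor signalling 3 of 16 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.587 with an estimated correlation), and 4 rose and none fell after the correction (adjusted p = 0.39). B2M, the MHC class I light chain, went from 1788 ± 52.9 to 3155 ± 201 TPM (SD, n = 3), and 8 of 24 antigen presentation genes rose and 1 fell, 8 and 2 adjusted over the list alone (adjusted p = 0.0861 with an estimated correlation). After the correction 12 rose and none fell, with an adjusted p = 0.00824.

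IFNB1 was listed at 0 in 10 of the 12 libraries, with 0.108 TPM in siNC poly(dA:dT) replicate 3 and 0.226 TPM in siQ61K poly(dA:dT) replicate 1. IFNL1 was above 0 in siQ61K poly(dA:dT) replicate 2 (0.356 TPM). Of the type I and III interferon list only IFNE was tested, and it was called higher by knockdown with poly(dA:dT) (log2 fold change 0.95, SE 0.23, adjusted p = 0.0114), though not without siQ61K poly(dA:dT) replicate 3 (adjusted p = 0.0524). Under siQ61K limma called 3712 genes after poly(dA:dT), 1019 higher (27.45%) and 2693 lower, with 50.25% higher under median-of-ratios scaling and 47.74% under quantile normalization, which moved the median of all genes from -0.15 to -0.02 and -0.01. This count followed GC content (Spearman -0.572 across genes), with 35 higher and 1621 lower among the 3575 genes with the highest GC. It was 1250 after the correction (61.84% higher) and 142 with the residual component as a covariate (69.01% higher). Without siQ61K DMSO replicate 3 and siQ61K poly(dA:dT) replicate 2 it was 137 (70.07% higher). In each of these fits most calls were higher rather than lower, with 62, 42 and 38 interferon-alpha list members among the higher ones. Component scores were 16.3, 9.88 and 32.5 in siQ61K DMSO and 16.5, -46.3 and -25.3 in siQ61K poly(dA:dT). As the scores differed between these groups, the covariate could take up part of the response itself. Without both libraries fewer were left per group, and 3876 genes still had an unadjusted p under 0.05. Left out singly, siQ61K DMSO replicates 1 and 3 gave 2276 and 2176 genes, and siQ61K poly(dA:dT) replicates 2 and 3 gave 1640 and 1628. Across all genes the responses to poly(dA:dT) under siNC and siQ61K correlated at Pearson -0.176 and Spearman -0.290. After the GC and length correction these were -0.00785 and -0.0428.

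**Figure D3:**
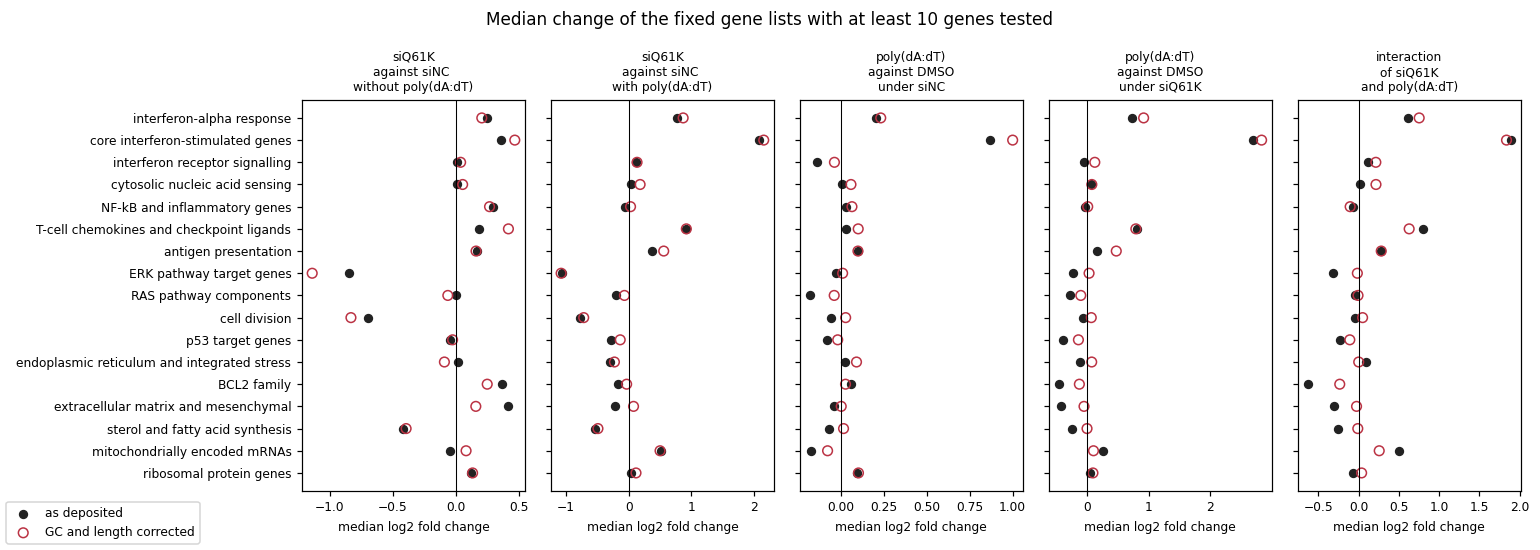
Median log2 fold change of each fixed list with at least 10 genes tested, in the 5 comparisons, as deposited (filled) and after the GC and length correction (open). The core interferon-stimulated genes had a median of 1.89 in the interaction as deposited and 1.84 after the correction.

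The interaction asked whether the response to poly(dA:dT) differed between siRNAs. It did for interferon-stimulated genes, which responded more under siQ61K. IFI44L responded more by 3.59 (SE 0.27, adjusted p = 4.5e-05), IFI44 by 3.01 (SE 0.20, adjusted p = 2.5e-05), IFIT1 by 2.11 (SE 0.21, adjusted p = 0.000391) and DDX58 by 2.24 (SE 0.18, adjusted p = 5.99e-05) on the log2 scale. In the core list 27 of 32 were higher and none lower, 28 adjusted over the list alone (adjusted p = 0.0331 with an estimated correlation, and 0.00739 after the GC and length correction). In the interferon-alpha response list 43 of 93 were higher and 2 lower, 45 and 5 adjusted over the list alone (adjusted p = 0.112 with an estimated correlation, and 0.00739 after the correction). ERK targets were lower in 9 of 33 and higher in none, and in none of 32 after the correction. The mean log2 score of the interferon-alpha list differed by 0.72 between responses (exact permutation of siRNA labels within treatments, two-sided p = 0.1; the smallest possible is 0.005), and exchanged labels in that test also carry the knockdown effect.

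Across all genes limma called 2662 in the interaction, 883 higher (33.17%) and 1779 lower, with 45.74% higher under median-of-ratios scaling and 46.53% under quantile normalization. These calls followed GC content (Spearman -0.656 across genes). Among the 3575 genes with the lowest GC 491 were higher and 11 lower, and among the 3575 with the highest 21 and 1295. After the correction 297 were called, 246 of them shared, and most were higher (201, 67.68%) rather than lower (96). Of 77 named genes called in the interaction, 45 kept the call whichever library was left out and 26 of 74 kept it after the correction. The count of 2662 was 980 and 1577 without siNC DMSO replicates 1 and 2, 1273 and 1640 without siNC poly(dA:dT) replicates 1 and 2, 1388 without siQ61K DMSO replicate 1, and 1372 and 1070 without siQ61K poly(dA:dT) replicates 2 and 3.

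**Figure D4:**
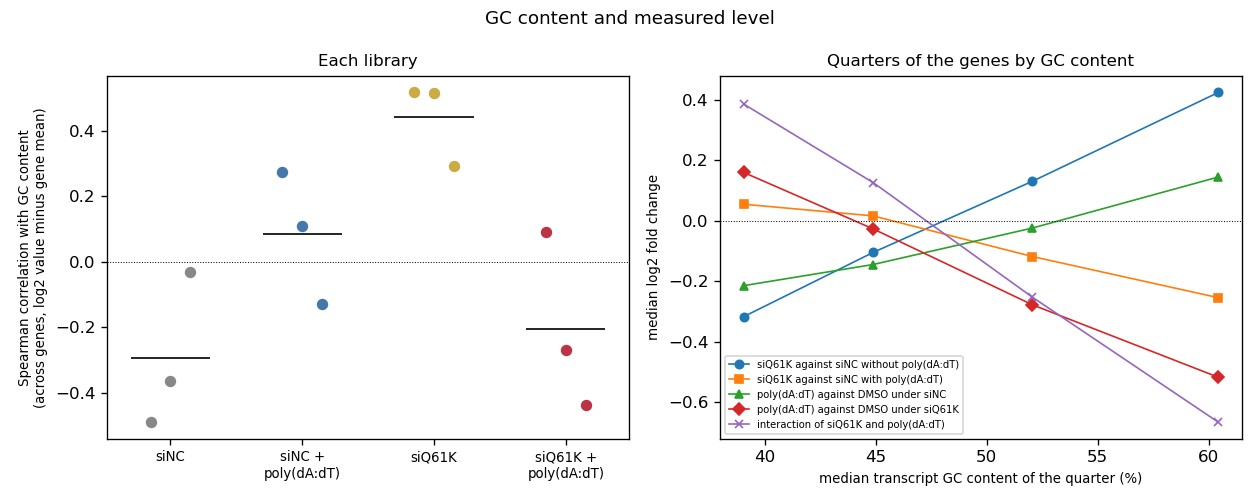
Spearman correlation of each library's deviation from the gene means with GC content, and median log2 fold change in 4 bins of genes by GC content, per comparison. Libraries ranged from -0.49 in siNC DMSO replicate 1 to 0.517 in siQ61K DMSO replicate 1, and differed within groups.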

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

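The tests of the residual component and of near-identical gene copies, the splits for the interaction, and the GC and length correction were chosen after the results were seen. Effects that differed between the siRNAs by the interaction test are given here, with log2 differences between the responses to poly(dA:dT).

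Interferon-stimulated genes responded more under siQ61K. The core list had a median of 1.89, with IFI44L at 3.59, IFI44 at 3.01, BST2 at 2.98 and IFIT1 at 2.11. Scaling between libraries as the whole cause is argued against by at least 43 interferon-alpha list members called higher under 3 other scalings, and GC content and length by 41 called higher after the correction. The residual component as the whole cause is argued against by the list score, which differed by 0.72 (SE 0.09) without it and by 0.85 (SE 0.08, lower 95% bound 0.673) with it as a covariate. Calls fell from 43 to 28 there as errors grew and fewer genes were called: the 15 members whose call ended had a median of 0.99 (median SE 0.28) before and 1.00 (median SE 0.32) after. A stronger response after loss of mutant NRAS is a candidate explanation that stays open, and it cannot be told apart from other effects of siQ61K. A difference between siRNA arms in how much poly(dA:dT) entered the cells also stays open and was not tested.

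The count of 2662 genes differing in response, most of them lower, may in large part reflect GC content. The fold changes correlated with GC content at -0.656 across genes, and the count was 297 after the correction, of which 201 were higher and 96 lower. The fold changes also correlated at -0.488 with the residual component, with 199 calls, 103 higher and 96 lower, when it was a covariate. That covariate could take up part of a real difference, since its scores differed between groups. Whether 1 library made the count cannot be told apart, since the lowest count with a library left out was 980 (without siNC DMSO replicate 1). The drop was not particular to that library. The count was 1070 without siQ61K poly(dA:dT) replicate 3 and 1273 without siNC poly(dA:dT) replicate 1, but 3886 without siQ61K poly(dA:dT) replicate 1. The correction may also remove responses that are real and differ by GC content, so the 2662 and 297 are not bounds on the biology.

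Other splits of the libraries bear on the counts of calls. For the interaction the additive effects of siRNA and poly(dA:dT) were first removed, since exchanged siRNA labels would otherwise carry the knockdown itself. Of 100 drawn splits 1, the real one, gave as many genes as the real 2662, with a highest other of 1542. Chance is not excluded by this, since the effects removed were fitted with the real labels and the interaction itself stayed in the values. That favours the real split, and the split with the siRNA labels exchanged within 1 treatment gave 0 genes. With those effects kept, as first planned, the split that exchanged the siRNA labels within 1 treatment gave 4502. The other comparisons had 10 splits each, too few for a share under 0.05, with 1 split as large as the real one in each: 4632 genes and a highest other of 1, 3144 and 3, 18 and 1, and 3712 and 1, for knockdown without and with poly(dA:dT) and poly(dA:dT) under siNC and siQ61K. In these comparisons the real effects were kept, so any other split moved the group difference into the spread and was bound to give few calls. The low counts of those splits therefore do not measure false calls.

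Several genes with extreme differences were listed at 0 in some libraries. FOXD1-AS1 had a fitted difference of 10.06, ARMCX7P of 3.25 and SRP9P1 of -4.31, each with 0 in every library of at least 1 group. RPL23AP42, at 12.01, and FABP5P7, at -7.62, were at 0 in 3 libraries each but in no whole group. SRP9P1 was listed at 0 in all libraries but those of siQ61K DMSO, with 23.6, 63.2 and 3.89 TPM, so its fitted value is no fold. The 22 tested genes listed at 0 in every library of 1 group and at 5 TPM or more on average in another had, over the 90.9% with a known length, a median longest transcript 0.151 times that of all genes tested (493 against 3256 nucleotides), and short transcripts are a candidate source of unstable TPM estimates. Reads shared between near-identical copies cannot be told apart from other sources, with 18.2% of these genes having such copies against 14.2% of all genes tested (Fisher exact test, one-sided p = 0.384).

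Further differences were FHL1 at 4.26, TREX1 at 2.80, RPL21 at 2.68, MT-ATP8 at 2.64, EIF4A3 at -4.04, MEX3C at -2.60, PKD1P5 at -2.51, GUSBP14 at -2.48, H3-2 at -2.37, EIF3F at -2.28, MGAT2 at -2.24 and H2AC8 at -2.21. Genes of the fixed set that differed were CXCL10 at 1.30, HLA-B at 0.73, IRF3 at -0.89 and ETV4 at -0.85. The difference for HLA-B did not become smaller after the GC and length correction. Its knockdown effects there were 0.33 without and 1.55 with poly(dA:dT), from 0.63 and 1.36. After the GC and length correction IRF3 (-0.30, SE 0.22, from SE 0.23), ETV4 (-0.21, SE 0.15, from SE 0.21) and CXCL10 (0.75, SE 0.36, from SE 0.36) were no longer called, with adjusted p = 0.487, 0.46 and 0.273, each because the difference became smaller. The calls of MT-ATP8 (2.17, SE 0.52, from SE 0.56) and PKD1P5 (-1.49, SE 0.42, from SE 0.43) ended with adjusted p = 0.0558 and 0.0856, as the differences became smaller and fewer genes passed the adjustment over all genes there (297 against 2662). The calls of ARMCX7P (3.18, SE 0.93, from SE 0.88), TREX1 (3.43, SE 0.93, from SE 0.83), EIF3F (-2.48, SE 0.70, from SE 0.66) and MGAT2 (-2.25, SE 0.71, from SE 0.68) ended with adjusted p = 0.0931, 0.0761, 0.0866 and 0.113, with fewer genes passing the adjustment. GUSBP14, H3-2 and H2AC8 had no GC content and were not in that fit.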

How the results depend on the processing

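The GC and length correction, the residual component as a covariate and the fit without both standout libraries (siQ61K DMSO replicate 3 and siQ61K poly(dA:dT) replicate 2) were chosen after the results were seen. NRAS kept its direction and call in both knockdown comparisons under all alternatives run, at -1.79 to -1.29 without and -1.17 to -0.98 with poly(dA:dT). Genes called with sample weights were 7588 for knockdown without poly(dA:dT), 332 for poly(dA:dT) under siNC and 5580 for the interaction. With no filter, which adds genes to the adjustment, poly(dA:dT) under siQ61K gave 2328 and the interaction 1026. After the GC and length correction the counts were 29 for poly(dA:dT) under siNC, 1250 under siQ61K and 297 for the interaction; with the residual component they were 142 under siQ61K and 199 for the interaction, without both standout libraries 137 and 550, and with only the 2 groups compared 2207 under siQ61K. Interferon-alpha list members higher after poly(dA:dT) under siNC were 11 with a pseudocount of 0.1, 17 with sample weights, 11 after the GC and length correction and 4 with only the 2 groups, and for the interaction 28 with the residual component, where the median of the list was 0.67 against 0.62. The interferon-alpha list score, in the order knockdown without and with poly(dA:dT), poly(dA:dT) under siNC and siQ61K, and interaction, was 0.35, 1.09, 0.47 and 1.22 for the first 4 with a pseudocount of 0.1, and 0.76, 0.22, 0.79 and 0.57 for the last 4 with a pseudocount of 5. For knockdown with poly(dA:dT), poly(dA:dT) under siQ61K and the interaction it was 1.06, 1.18 and 0.80 with median-of-ratios scaling and 1.06, 1.21 and 0.83 after the GC and length correction, and for the last 2 of these 1.19 and 0.81 with quantile normalization. The pseudocount shifts follow from the scale; for the rest the cause was not tested. Across left-out libraries the calls ranged from 3045 to 4998, 2108 to 3750, 7 to 37, 1628 to 4608 and 980 to 3886 in the same order, the list members higher after poly(dA:dT) under siNC from 4 to 9, and the score from 0.86 to 1.05 for knockdown with poly(dA:dT), 0.93 to 1.09 for poly(dA:dT) under siQ61K and 0.60 to 0.77 for the interaction. The correlation of the knockdown effects ranged from 0.196 to 0.370 and was 0.486 after the GC and length correction. Signs changed after that correction for HRAS by knockdown without poly(dA:dT) (-0.23, adjusted p = 0.0466) and ETV4 by poly(dA:dT) under siQ61K (0.0138, adjusted p = 0.953). Whether replicate numbers pair the samples was not settled. The 18 same-number pairs correlated at -0.26 to 0.233, 3 of them over 0.1. In 19 of 36 matches, each among 3 libraries, the own number was best. Between siNC poly(dA:dT), siQ61K DMSO and siQ61K poly(dA:dT) all same-number pairs were positive, from 0.0401 to 0.233. Same-number pairs with siNC DMSO ran from -0.26 to 0.037. With a replicate block the calls were 4436, 2957, 22, 3433 and 2243. Depth is unknown, so what it limits cannot be stated.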

Other observations

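The GC and length correction was chosen after the results were seen. Stress, cell death and other gene lists had calls in both directions. After knockdown with poly(dA:dT), endoplasmic reticulum and integrated stress genes fell in 12 of 25 and rose in 4, 12 and 6 adjusted over the list alone, with ASNS, an asparagine synthesis enzyme, at -1.31 and VEGFA at -1.01 (adjusted p = 0.256 with an estimated correlation). Without poly(dA:dT) 8 fell and 2 rose, also when adjusted over the list alone (adjusted p = 0.708 with an estimated correlation), with ASNS at -1.39. Of 27 p53 targets 9 fell and 4 rose, 11 and 5 adjusted over the list alone, with GDF15 at -1.64 (adjusted p = 0.634 with an estimated correlation), and after the GC and length correction 10 fell and 7 rose. Without poly(dA:dT) 7 p53 targets rose and 5 fell, 8 and 5 adjusted over the list alone (adjusted p = 0.943 with an estimated correlation), with TP53I3 at 1.69, BBC3 at 1.23 and PHLDA3 at 1.11 (1.38, 0.64 and 0.74 after the correction). In the BCL2 family 6 of 14 fell and 2 rose, 6 and 3 adjusted over the list alone, with BCL2A1 at -1.20 (adjusted p = 0.624 with an estimated correlation), and after the correction 6 fell and 4 rose. Without poly(dA:dT) 4 of the family rose and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.651 with an estimated correlation), with BOK at 1.55 (1.01 after the correction), BMF at 1.29 and BCL2A1 at -1.90. Of 29 RAS pathway components 3 fell and 2 rose, also when adjusted over the list alone, with RRAS2 at 0.74 (adjusted p = 0.73 with an estimated correlation), and without poly(dA:dT) 6 fell and 5 rose, also when adjusted over the list alone (adjusted p = 0.943 with an estimated correlation).

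Mitochondrially encoded mRNAs were higher in 4 of 13 after knockdown with poly(dA:dT) and lower in none, also when adjusted over the list alone, with MT-ND3 at 4916 ± 248 TPM under siNC and 8365 ± 1137 TPM under siQ61K (SD, n = 3; adjusted p = 0.448 with an estimated correlation for the list). Without poly(dA:dT) none were higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.943 with an estimated correlation): MT-ND3 at -0.78, MT-ATP8 at -1.42 and MT-ND4L at -1.24. After the GC and length correction 1 was higher and none lower there, with smaller differences for MT-ND3 (-0.38, SE 0.16, from SE 0.14, adjusted p = 0.0935), MT-ATP8 (-0.99, SE 0.37, from SE 0.40, adjusted p = 0.065) and MT-ND4L (-0.94, SE 0.33, from SE 0.35, adjusted p = 0.0535). The mitochondrial share of siQ61K poly(dA:dT) replicate 2 was 4.70%, the highest of the 12 libraries. Ribosomal protein genes rose in 6 of 47 and fell in 1 after knockdown with poly(dA:dT), 3 and 1 adjusted over the list alone (adjusted p = 0.593 with an estimated correlation). Without poly(dA:dT) 13 rose and 4 fell, 14 and 4 adjusted over the list alone (adjusted p = 0.916 with an estimated correlation), and 8 and 3 after the correction. Of the markers of other cell types 2 were tested, and CD68 fell by 0.77 on the log2 scale after knockdown without poly(dA:dT).

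Some abundant or known genes had unusual levels in the deposited values. ISG15, usually a strong interferon-stimulated gene, was listed at 0 in all siNC DMSO libraries and reached 4.90 TPM in siQ61K poly(dA:dT) replicate 2. EIF4A3 was at 34.4, 15.6 and 13.5 TPM in siQ61K DMSO and at most 1.00 TPM in the other libraries.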
